A study of Equus caballus with 32 samples.

How the data were processed

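Venous blood of 32 Welsh Pony mares was collected 30 days after their foals were weaned, into tubes with a reagent that stabilises RNA. According to the labels, 16 mares had a brutal weaning and 16 a progressive weaning, and each mare gave 1 array. The labels do not describe the weaning procedures further, and they pair no mares between the groups. No paired analysis was possible because no label links a mare of one group to a mare of the other. Total RNA was extracted from the whole blood, and 200 ng per mare were amplified to cRNA labelled with Cy3 and hybridised to single-colour Agilent arrays. The 32 arrays lie on 4 slides of 8 arrays, with 4 mares of each group on every slide, and each slide was scanned 1 time. On each slide the arrays stand in 2 rows, and over the 4 slides each group has 8 arrays in each row.

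The deposited scanner files hold intensity values per spot, extracted per the file headers with Agilent Feature Extraction 10.10.1.1, which subtracted the background and removed spatial trends. The deposited series table holds log2 values that share 1 distribution over the arrays. Its medians per array ran from 8.397 to 8.399, and the tool that normalised it is not given in the sources used here. Each column of that table was checked against the scanner files, and the rank correlation across spots was at least 0.996 with its own array and at most 0.987 with any other array. Probes are annotated by the file headers on an older horse assembly, so no coordinates are given.

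Of 62976 spots, 1319 were controls and were left out, and the other 61657 belonged to 43987 probes. Spots marked by the extraction software as outliers were left out, 2483 over all arrays, of which 851 lay on the array progressive 16. No spot was saturated. The processed signal was divided by its array's 75th percentile over all non-control probes, turned to log2, and averaged over the spots of a probe. A probe was tested when it stood well above background on at least 8 of the 16 arrays of a group, which left 26368 probes. Gene names came from the files for 23883 probes, from a reference table by accession for 2973, by gene ID for 1237 and by synonym for 69, and from older names in the files for 1340, while 14485 probes had no name. A gene was represented by its brightest tested probe over all arrays, which gave 9392 genes of 15063 symbols on the array. Older and current symbols of a gene count as separate genes where the reference table does not join them. Of 3806 genes with several tested probes, 1672 had only probes that overlap in sequence by at least 15 bases, and the probes of such a gene are not separate measurements.

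Differences are progressive minus brutal, from limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the group as the only term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The error given beside a difference is limma's standard error (SE), and intervals are at the 95% level. Gene lists were 16 pathways and 14 sets of cell type markers, 30 in all, fixed before the data were examined. Camera of limma, with a preset correlation of 0.01 between genes, compared the 26 lists with at least 5 measured members against all other genes. Camera with the correlation estimated for each list and fry were run beside it. The directional p of fry tests whether the genes of a list move, on balance, one way, its mixed p whether they change in either direction, and neither compares the list with other genes. A list score per array, the mean z value of the measured members, was compared by a permutation test with 100000 relabellings, adjusted over the 30 lists. The share of the squared distances between arrays that lies between the groups was tested in the same way, and for a slide alone by an exact permutation test over its 70 relabellings. The permutations and correlations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9.

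Named genes followed a rule set before the data were examined. It takes up to 12 genes per direction past the threshold, filled to 10 with the smallest unadjusted p where fewer pass, and then named as not past it. It adds the 2 members with the smallest p of each list, 4 where the list was called by camera, and always FKBP5, TSC22D3, PER1, NR3C1, HBB, S100A8 and ALAS2. It took 91 genes, of which 87 were carried on and 4 are not reported. Genes named outside it were chosen after their values were seen, and the text says so.

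The alternatives were normexp background correction with an offset of 50, quantile normalisation, the 75th percentile over probes detected on all arrays, the series table, slide as a block, each slide alone, each slide left out, slide with array row, no filter on dim probes, a stricter filter, covariates for blood composition, eBayes with trend and robust options, array weights, an adjusted p of 0.10, and the mean of a gene's probes. The composition covariates were the neutrophil, T cell, erythroid and platelet scores. Leaving out the array progressive 16 was added after seeing the data, and so were both filter alternatives for the gene lists. The trend and robust options and the array weights were not run for the lists. The fit was also repeated on 100 splits of the 32 arrays into groups of 16, the real split included.

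The 75th percentile of the processed signal ran from 339.5 to 646 intensity units per array, and 53.0 to 66.0% of the spots stood well above background. The number of arrays limits the precision. The fit was tested on simulated data, 20 runs with 200 changed genes of 9392 at 16 against 16 arrays, for the comparison of progressive with brutal. It recovered 20.5% of the genes changed by 0.25 on the log2 scale, 68.2% of those changed by 0.5 and 95.8% of those changed by 1. Of its calls 2.3% were false. With 200 changed genes the adjusted threshold is easier to pass than with few. These shares therefore do not give the power to find only a few changed genes. A list of 20 random genes shifted by 0.25 was called in 20 of 20 runs, with the preset and with the estimated correlation. These calls were made without adjustment over other lists. Genes drawn at random do not show the power for lists of correlated genes. The estimated correlation was 0.229 in the platelet list and 0.749 in the cell cycle list, and no such list was simulated.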

Results

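Gene expression was measured in the whole blood of 32 Welsh Pony mares, 30 days after weaning of their foals, on 1 array per mare. In 16 mares the weaning was brutal and in 16 it was progressive. The arrays' 75th percentile signal ran from 339.5 to 646 intensity units, and 53.0 to 66.0% of the spots of an array stood well above background. Expression values are log2 signals relative to the array's 75th percentile, so that 0 is the level of that percentile.

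The comparison asks whether the kind of weaning leaves a trace in the mares' blood transcripts 30 days later. No single gene separated the groups past the threshold. The 2 genes with the smallest p among those lower after progressive weaning were MVK (mevalonate kinase, an enzyme of sterol synthesis) and PROS1 (protein S, an anticoagulant cofactor). Among those higher they were ARMC12 (an armadillo repeat protein) and FKBP5 (a co-chaperone of the glucocorticoid receptor that glucocorticoids induce). FKBP5 averaged 2.86 ± 0.23 (SD, n = 16) after brutal and 3.30 ± 0.49 (SD, n = 16) after progressive weaning, a 1.36-fold ratio. MVK averaged -4.24 ± 0.46 (SD, n = 16) and -4.96 ± 0.55 (SD, n = 16), a ratio of 0.605, near the background on some arrays. As groups of genes, platelet, neutrophil, erythroid, inflammatory and respiratory chain transcripts were mostly lower and cell cycle transcripts mostly higher after progressive weaning. For the respiratory chain this direction depended on the scaling. On slide 2 alone the platelet and erythroid medians lay on the other side of 0. So did the cell cycle median on slide 3 alone, the respiratory chain median on slide 1 alone and the erythroid median without slide 3. None of these 6 lists passed once the correlation between their genes was estimated.

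Limma called 0 of 26368 probes and 0 of 9392 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.996 at both levels. At an unadjusted p under 0.05 there were 726 probes, 2.75% of those tested, and 244 genes. The options trend and robust of eBayes gave 0 genes and 238 at an unadjusted p, and array weights gave 0 genes and 457. With slide as a block, limma gave 0 probes and 786 at an unadjusted p. Of the 726 probes, 230 were higher and 496 lower after progressive weaning. This balance moved with the scaling, to 96 higher and 540 lower with normexp and to 303 higher and 396 lower with the 75th percentile of probes detected on all arrays. The median difference over all probes was -0.014, and it lay between -0.027 and 0.0078 under the other scalings. Of all 9392 genes, 5472 were lower and 3920 higher (41.7%), with a median of -0.020, which is the background for the counts of list members given here.

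The genes named below did not pass the threshold, and the adjusted p of each was at least 0.996. Among the 10 lower genes with the smallest unadjusted p, MVK differed by -0.72 (SE 0.17, p = 0.000179) and PROS1 by -0.71 (SE 0.17, p = 0.00029), both lower on 4 of 4 slides. ECATH-2, an equine cathelicidin that serves as an antimicrobial peptide, averaged 1.01 ± 0.82 (SD, n = 16) after brutal and 0.03 ± 0.90 (SD, n = 16) after progressive weaning, a difference of -0.97 (SE 0.29, p = 0.00186). PRKCDBP, a caveolar protein, differed by -1.38 with an SE of 0.45. P2RY11, a purinergic receptor, differed by -0.50, NECAP2 (an endocytic adaptor) by -0.23, SETD8 (a histone methyltransferase) by -0.22, GNG11 (a G protein gamma subunit) by -0.45, SELENBP1 (a selenium-binding protein) by -0.47, and CDS2 (a phospholipid synthesis enzyme) by -0.49. Among the 10 higher genes, ARMC12 differed by 0.58 (SE 0.17, p = 0.00188), higher on 3 of 4 slides, and FKBP5 by 0.44 (SE 0.13, p = 0.00217), higher on 4 of 4 slides. WNT5B (a secreted Wnt ligand) differed by 0.66, NXF2 (an RNA export factor) by 0.67, HIBCH (an enzyme of valine breakdown) by 0.52, COX15 (an enzyme of haem A synthesis) by 0.38, RAB39B (a small GTPase) by 0.34, RBM41 (an RNA-binding protein) by 0.36, TERF1 (a telomere repeat-binding protein) by 0.28 and USP44 (a deubiquitinase) by 0.40. Several of these genes were dim, with WNT5B, NXF2 and HIBCH well above background on 13, 18 and 15 of 32 arrays, RBM41 and USP44 on 23, COX15 and MVK on 25, PRKCDBP on 27 and RAB39B on 28. Of these 20 genes, 18 kept their direction on all 4 slides and 2 on 3 slides. They were picked for the smallest p over these same arrays, so such agreement is expected from the choice and adds no support.

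**Figure D1:**
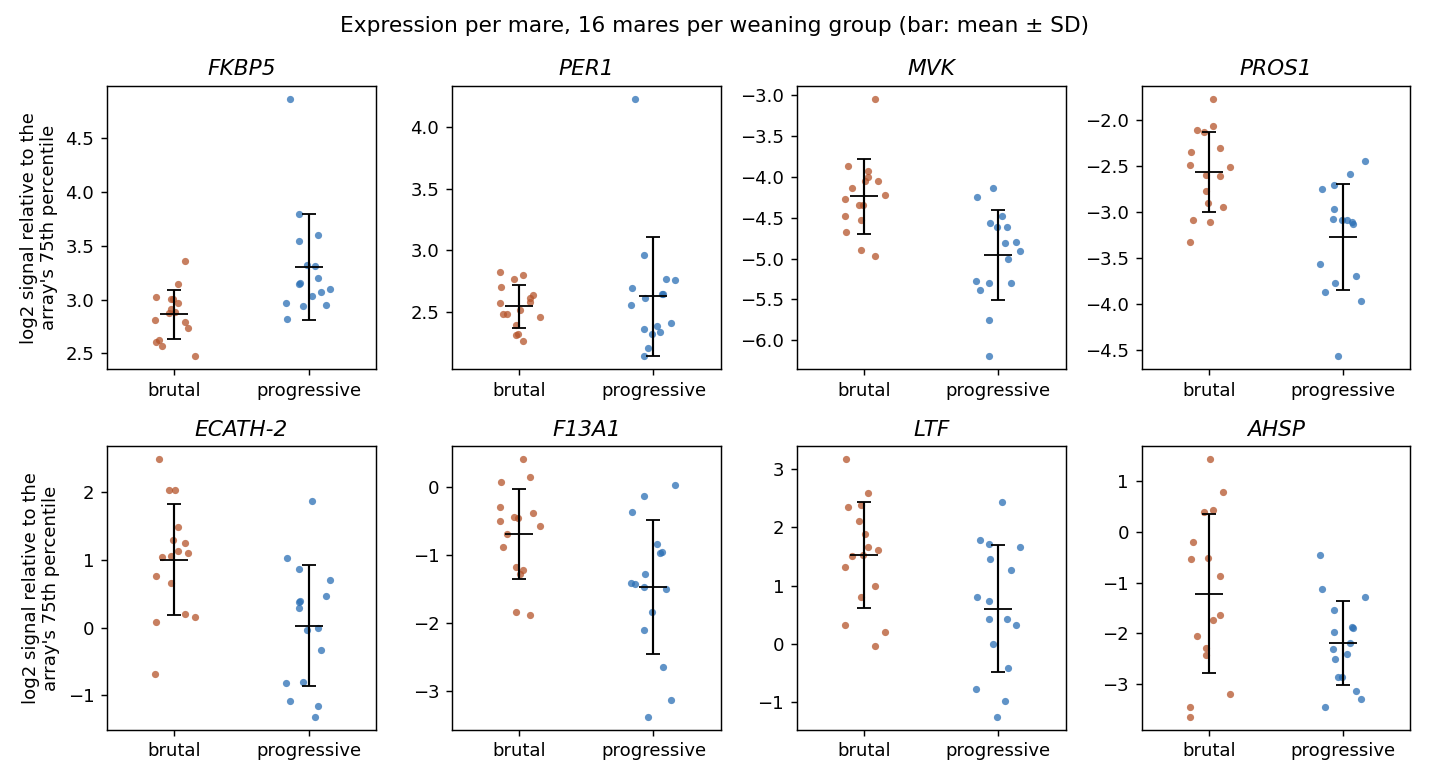
Log2 signal relative to the array's 75th percentile (vertical axes) of 8 genes in the 16 mares per group, with 1 point per mare and bars for the mean ± SD. FKBP5 was higher after progressive weaning by 0.44, with 1 mare at 4.87, and MVK, PROS1, ECATH-2, F13A1, LTF and AHSP were lower, while the groups overlapped for each gene and none passed the threshold.

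Transcripts of platelets and their precursors were lower after progressive weaning in 13 of 15 measured genes, with a median difference of -0.34. F13A1 (coagulation factor XIII A chain) differed by -0.77 (SE 0.28), PF4 (platelet factor) by -0.37, TREML1 (a receptor of platelet granules) by -0.49 and VWF (von Willebrand factor) by -0.56. Camera called the list with a preset correlation (adjusted p = 0.000422) and did not with an estimated one (adjusted p = 0.663 with an estimated correlation). With slide as a block the preset adjusted p was 0.000543. The list's unadjusted p values were 0.0383 with an estimated correlation, 0.0332 by fry and 0.0321 by permutation of the list score, which differed by -0.41, and the permutation p adjusted over 30 lists was 0.481. The permutation p within slides was 0.0413. On slide 2 alone the median was 0.092, on the other side of 0, without slide 1 the preset adjusted p was 0.068, and on slide 4 alone the list was not called. No member passed, adjusted over the list alone. The 4 measured endothelial markers, of which VWF also stands in the platelet list, were all lower, with a median of -0.26 and ROBO4 (a vessel wall receptor) at -0.26. Their score differed by -0.52 (permutation p = 0.00175, adjusted p = 0.0525 over 30 lists), and the permutation p within slides was 0.0017. Camera did not test so short a list, and with no filter on dim probes it called the endothelial list lower (8 of 10 members, preset adjusted p = 0.0205), where no correlation was estimated.

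Neutrophil genes were lower after progressive weaning in 15 of 18 measured genes, with a median difference of -0.17. LTF (lactoferrin, stored in granules) averaged 1.52 ± 0.90 (SD, n = 16) after brutal and 0.60 ± 1.08 (SD, n = 16) after progressive weaning. It was lower on 4 of 4 slides, but was picked for its small p over these same arrays. NCF1 (a subunit of the NADPH oxidase) differed by -0.30, ALPL (alkaline phosphatase) by -0.37 and PADI4 (a protein deiminase) by -0.40. S100A8 (a calgranulin) differed by -0.31 (SE 0.31) and was lower on only 2 of 4 slides. The preset adjusted p was 0.0063, and it was 0.00674 with slide as a block and 0.713 with an estimated correlation. The score differed by -0.327 (permutation p = 0.158, within slides 0.158). Without slide 3 the preset adjusted p was 0.0618, and the list was not called on slide 4 alone.

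Erythroid genes were lower in 12 of 14 measured members, with a median of -0.081 and a mean of -0.279. Its members included SELENBP1, AHSP (a chaperone of alpha globin) at -0.97 with an SE of 0.42, ALAS2 (the first enzyme of haem synthesis in red cells) at -0.66 with an SE of 0.39, and HBB (beta globin) at -0.39 with an SE of 0.55. The preset adjusted p was 0.0343, and it was 0.0346 with slide as a block and 0.713 with an estimated correlation. The score differed by -0.298 (permutation p = 0.135, within slides 0.148). Of the 10 members well above background on all arrays 9 were lower, with a median of -0.24. The direction was not shared by the slides, with a median of 0.35 on slide 2 alone and -0.51 on slide 3 alone. On slide 2 alone the preset test also called the list (adjusted p = 0.0272), with its median on the other side of 0. Without slide 3 the median was 0.029 and the preset adjusted p 0.454.

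Inflammatory cytokine genes and targets of NF-kB were lower in 18 of 22 measured members, with a median of -0.16. IL1RN (the interleukin 1 receptor antagonist) differed by -0.37 (SE 0.14), IL1B (interleukin 1 beta) by -0.32, NFKB2 (an NF-kB subunit) by -0.17 and RELB (another subunit) by -0.22. IL1RN blocks the receptor on which IL1B acts, so the list's members with the smallest p act in both directions on inflammation. The preset adjusted p was 0.0343, and it was 0.0346 with slide as a block and 0.663 with an estimated correlation. The score differed by -0.264 (permutation p = 0.0583, adjusted p = 0.583, within slides 0.0576). The preset call was lost with normexp (adjusted p = 0.052), with composition covariates (adjusted p = 0.311), without slide 1, without slide 2 and on each slide alone.

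Cell cycle genes were higher in 23 of 26 measured members, with a median of 0.12. AURKA (a mitotic kinase) differed by 0.18, BUB1B (a spindle checkpoint kinase) by 0.23, MCM6 and MCM7 (subunits of the replicative helicase) by 0.12 and 0.11, and no member had an unadjusted p under 0.05. The preset adjusted p was 0.000422, and it was 0.000209 with slide as a block and 0.725 with an estimated correlation. The score differed by 0.226 (permutation p = 0.477, within slides 0.439). On slide 3 alone the median was -0.042, without slide 4 the preset adjusted p was 0.0672, and the list was not called on slides 1, 2 and 3 alone. Genes of oxidative phosphorylation were lower in 61 of 70 members by a median of -0.047, with ATP5D at -0.24, ATP5F1D (a current symbol of the same ATP synthase subunit, kept apart by the files) at -0.21, NDUFB9 (a subunit of respiratory complex I) at -0.097 and ATP5MG (another ATP synthase subunit) at -0.13. The preset adjusted p was 0.0345, and it was 0.0412 with slide as a block and 0.76 with an estimated correlation. The score differed by -0.2 (permutation p = 0.499, within slides 0.511). The direction depended on the scaling, with a median of 0.0028 and 36 of 70 members higher under quantile normalisation. The preset call was lost under each of the 4 scaling alternatives and with composition covariates (adjusted p from 0.0503 to 0.957), without slide 3 or slide 4, on slides 1, 2 and 4 alone, and without the array progressive 16 (adjusted p = 0.201), where 53 of 70 members were lower, the median was -0.026 and the score differed by -0.122.

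**Figure D2:**
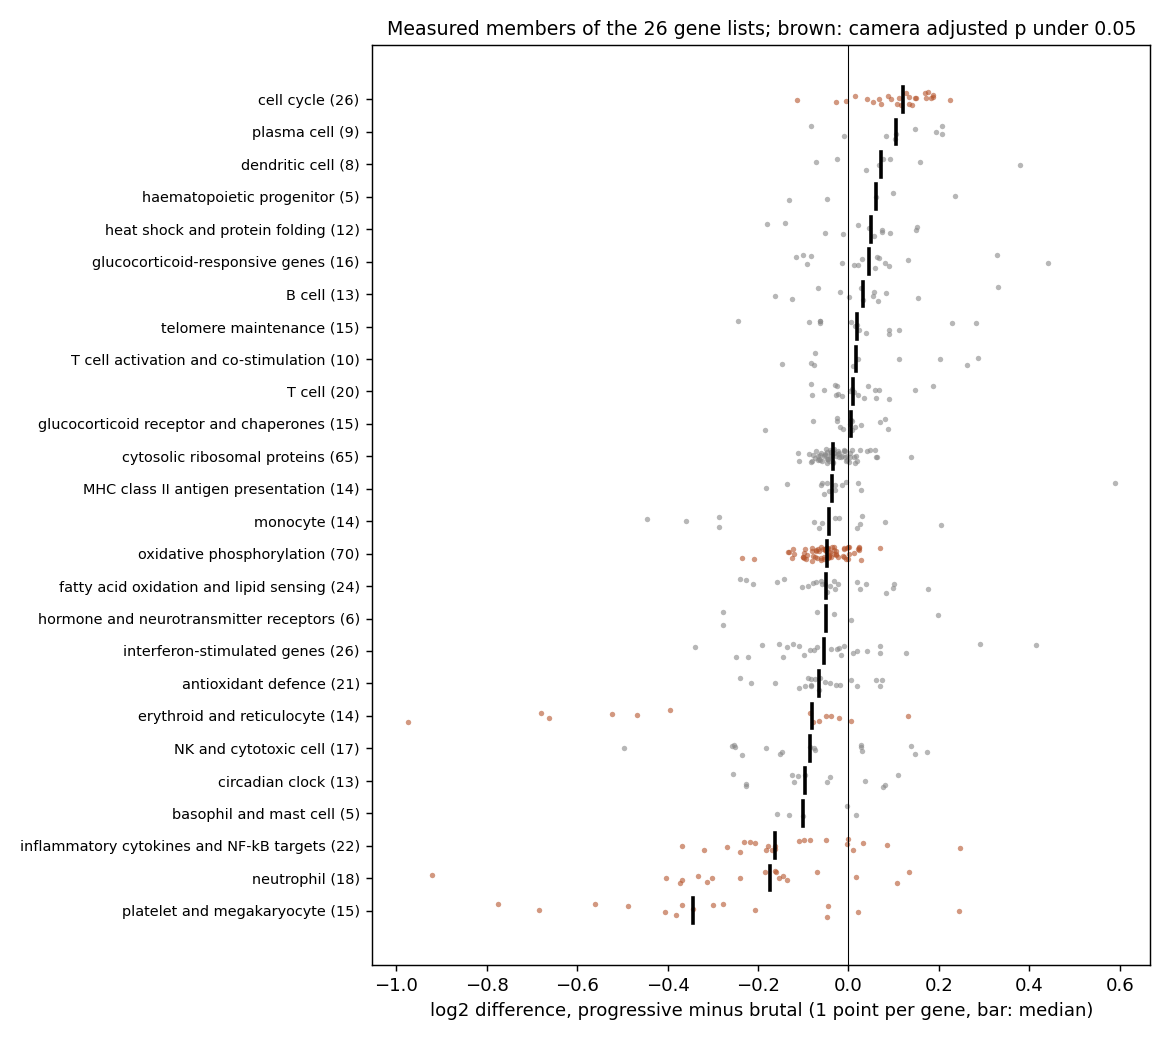
Log2 difference, progressive minus brutal (horizontal axis), of the measured members of the 26 gene lists tested by camera, with 1 point per gene, a black bar at each list's median and the number of measured members in brackets. The 6 lists in brown had a preset adjusted p under 0.05, with medians from -0.34 (platelet) to 0.12 (cell cycle). The oxidative phosphorylation median was 0.0028 under quantile normalisation, and the ribosomal, MHC class II and T cell activation medians also changed sign with the scaling.

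Genes that glucocorticoids induce were higher in 11 of 16 measured members, with a median of 0.045. FKBP5 was 1 member past 0.05 adjusted over the list alone (adjusted p = 0.0347 in limma), against 0 over all genes. That adjustment was made in each of 30 lists separately, so 1 such pass can come from chance. Among the other responders, TSC22D3 differed by 0.011 (SE 0.13), PER1 by 0.080 (SE 0.13) and SGK1 by -0.12, while IL1R2, chosen after its values were seen, differed by 0.33 (SE 0.36). The glucocorticoid receptor NR3C1 differed by -0.019, with a 95% interval of -0.15 to 0.11, and by 0.003 under the 75th percentile of probes detected on all arrays. The list was not called (preset adjusted p = 0.135, and 0.725 with an estimated correlation), and its score differed by 0.099 (permutation p = 0.636, within slides 0.638). The preset test called it higher with composition covariates (adjusted p = 3.52e-07, median 0.18), with normexp (0.0277), with the series table (0.0379), without slide 3 (0.00741) and on slides 1 and 2 alone (0.0495 and 0.0366), and lower on slide 3 alone (0.045, median -0.17). The array progressive 16 had the highest FKBP5 (4.87, next 3.80), PER1 (4.23, next 2.96), IL1R2 (3.36, next 1.92) and list score (1.66, next 0.87). Without that array the list's median was -0.015 and its score differed by -0.0080 (permutation p = 0.965), while FKBP5 differed by 0.34 (SE 0.091). FKBP5 differed by 0.65, 0.28, 0.060 and 0.77 on slides 1 to 4. The list of the receptor and its chaperones had 9 of 15 members higher, a median of 0.0051, a mean of -0.0026 and camera's direction up (adjusted p = 0.648), with BAG1 at -0.18 and HSP90AA1 at 0.080.

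**Figure D3:**
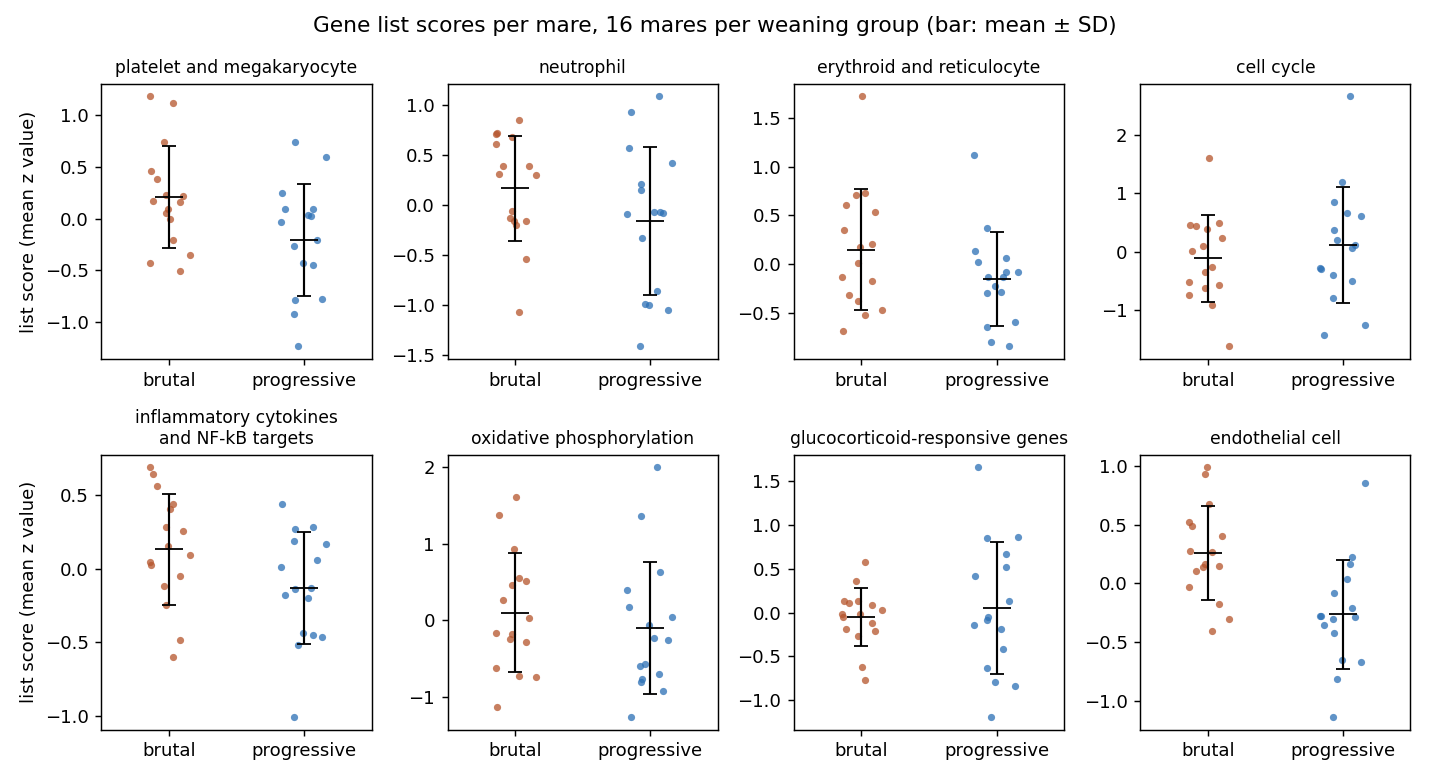
List scores (mean z value of the measured members, vertical axes) of 8 gene lists in the 16 mares per group, with 1 point per mare and bars for the mean ± SD. The platelet score averaged 0.205 after brutal and -0.205 after progressive weaning, and the groups overlapped for all 8 scores. The oxidative phosphorylation list, whose score differed by -0.2, had a median gene difference on the other side of 0 under quantile normalisation.

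In the reported fit, none of the other lists was called by camera with a preset correlation, with an estimated one (smallest adjusted p over all lists 0.663) or by fry (smallest 0.715). Among genes of defence, interferon-stimulated genes were lower in 18 of 26 (median -0.054), with IFI44 at 0.42 and ISG20 at -0.19, and MHC class II presentation genes in 11 of 14 (median -0.035, and 0.031 under quantile normalisation), with IFI30 at -0.14 and HLA-DMB at -0.18. T cell activation genes were higher in 6 of 10 (median 0.016, and -0.054 with normexp), with IL2RA at 0.29 and TBX21 at -0.15. Cytosolic ribosomal protein genes were lower in 50 of 65 (median -0.034), with RPL28 and RPLP2 both at -0.11, but higher in 53 of 65 under quantile normalisation, where the preset adjusted p was 0.000112, and in 52 of 65 with the series table (adjusted p = 4.62e-05, and 0.917 in the reported fit with an estimated correlation). Without the array progressive 16, 39 of 65 were lower, with a median of -0.0052. In metabolism, genes of fatty acid oxidation were lower in 17 of 24 (median -0.050), with HADH at -0.14 and ETFB at -0.21, and antioxidant genes in 16 of 21 (median -0.064), with PRDX5 at -0.16. Heat shock genes were higher in 8 of 12 (median 0.051), with HSPD1 at 0.15 and BAG3 at 0.15, and their preset adjusted p was 0.102, but 0.0343 under quantile normalisation, 0.00877 with normexp, 0.00928 with the series table, 0.0313 without slide 2 and 0.0377 with the stricter filter. In the reported fit it was 0.663 with an estimated correlation. Clock genes were lower in 9 of 13 (median -0.095), with the repressor BHLHE40 at -0.25 and the activator DBP at -0.23. Telomere maintenance genes were higher in 10 of 15 (median 0.019), with NAF1 at -0.24. Hormone and neurotransmitter receptors were lower in 4 of 6 (median -0.050), with RXRA at -0.28. Of 3 measured members of the list named for serotonin, opioid and catecholamine metabolism 2 were lower. KMO (kynurenine monooxygenase, an enzyme of tryptophan breakdown) was among them at -0.52. The list score differed by -0.283 (permutation p = 0.275, within slides 0.261).

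Among the other cell type markers, monocyte genes were lower in 9 of 14 (median -0.044), with the chemokine receptor CCR2 at -0.36 and TYMP at -0.29, and NK and cytotoxic genes in 11 of 17 (median -0.085), with KLRB1 at -0.50 and CRTAM at 0.17. Dendritic cell genes were higher in 6 of 8 (median 0.072, preset adjusted p = 0.0548), with CLEC9A at 0.38 and FLT3 at 0.16. The preset test called them higher with normexp (adjusted p = 0.0311), the stricter filter (0.0337), the mean of a gene's probes (0.0371), without slide 1 (0.0436), on slide 3 alone (0.0272) and without the array progressive 16 (0.0415). In the reported fit they had an adjusted p = 0.663 with an estimated correlation. B cell genes were higher in 9 of 13 (median 0.032), with PAX5 at 0.33 and FCRLA at 0.15, plasma cell genes in 7 of 9 (median 0.105), with CD38 at 0.21 and XBP1 at -0.082, and T cell genes in 12 of 20 (median 0.011), with LEF1 at 0.19 and CCR7 at 0.15. The preset test called T cell genes higher with normexp (adjusted p = 0.0311), without slide 4 (0.00724), on slide 2 alone (0.000218) and without the array progressive 16 (0.0415, with 15 of 20 higher and a median of 0.049), and plasma cell genes with normexp (0.0311) and composition covariates (0.00534). In the reported fit T cell genes had an adjusted p = 0.76 and plasma cell genes an adjusted p = 0.725 with an estimated correlation. With normexp it called 6 lists higher and 3 lower, against 1 higher and 5 lower in the reported fit. The interferon, ribosomal, T cell activation, antioxidant, clock, telomere, basophil, monocyte, B cell, NK and progenitor lists were also called on 1 or more slides alone or with 1 slide left out. Basophil and mast cell genes were lower in 4 of 5 (median -0.10), with SLC18A2 at -0.16 and KIT at -0.13, and the 3 measured eosinophil genes were all lower (median -0.11), with PTGDR2 at -0.11 and IL5RA at -0.13. Progenitor genes were higher in 3 of 5 (median 0.060), with MYB at 0.24. The 1 measured skin keratinocyte gene, SFN, differed by -0.26. Without the array progressive 16 other medians near 0 also moved by over 1.5 times, to -0.0085 for the glucocorticoid receptor and chaperone list, -0.011 for MHC class II, 0.042 for T cell activation, -0.042 for antioxidant, -0.054 for clock, 0.038 for telomere, -0.045 for basophil, -0.075 for monocyte and 0.057 for B cell genes, and none of these 9 lists was called. Adjusted over the list alone, no member of any list other than the glucocorticoid list passed.

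Over all tested probes together, the group explained 2.92% of the squared distances between arrays, against a mean of 3.22% over relabellings (permutation p = 0.556). With slide as a block the share was 3.25%, against a mean of 3.57% over relabellings (permutation p = 0.559). Within single slides it ran from 9.21% on slide 1 to 15.7% on slide 3, against a mean of 14.3% over the 70 relabellings of a slide (exact permutation p = 1.0, 0.971, 0.343 and 0.543 on slides 1 to 4). Slide explained 9.93%, against a mean of 9.68% over relabellings (permutation p = 0.386), and array row 3.47%, against 3.22% (permutation p = 0.308). The median SE of a gene's difference was 0.104 on the log2 scale and the median SD between mares of a group 0.295. For 8581 genes, 91.4% of those tested, the 95% interval of the difference lay within a 1.5-fold change in either direction, and for 9280 genes (98.8%) within a 2-fold change. Larger differences between the group means lay outside the intervals of those genes, and smaller ones inside them were not excluded.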

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

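Leaving out the array progressive 16, and the 2 changes of the filter on dim probes for the gene lists, were chosen only after the data were seen, and all other alternatives were fixed before. Limma called 0 genes under each of 22 alternatives, and 0 probes under 20 of 21, with 354 to 1372 probes at an unadjusted p under 0.05. The exception was 1 probe on slide 4 alone, for TCP11L1 (adjusted p = 0.00748), and under the other alternatives the smallest adjusted p of a probe ran from 0.677 to 1. The group's share of the squared distances stayed on its side of the threshold under 17 alternatives, with p from 0.325 to 1.0 (permutation, exact within slides). The count of probes at an unadjusted p, 726 in the reported fit, was 354 on slide 1 alone, 455 on slide 2 alone, 415 without slide 3 and 406 without slide 4, each with fewer arrays, and 1372 with array weights, where the cause was not tested. The count of 6 lists was 11 on slide 2 alone, 10 on slide 3 alone and 3 with composition covariates (4 lists left out), of which only cell cycle is among the 6, beside the glucocorticoid-responsive and plasma cell lists, all higher. It was 0 with an estimated correlation, 0 with fry and 0 by permutation of the list score, and the latter 2 also change what a list is compared with. For the estimated correlation the cause lies in its construction, and for the other counts it was not tested. The cell cycle list was called in the same direction under 15 of 22 alternatives (adjusted p from 1.52e-07 to 0.878), the inflammatory list under 11 of 22 (0.00242 to 0.715) and oxidative phosphorylation under 8 of 22 (0.00651 to 0.957). The neutrophil list was called under 16 of 21 (3.72e-05 to 0.978), the platelet list under 15 of 21 (2.74e-07 to 0.715) and the erythroid list under 13 of 21 (4.29e-11 to 0.978).

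Of 1456 differences of the 87 named genes under alternatives other than single slides, 1440 kept their direction and none passed the threshold. List medians changed sign for platelet genes on slide 2 alone (0.092), cell cycle on slide 3 alone (-0.042), erythroid genes on slide 2 alone (0.35) and without slide 3 (0.029), and oxidative phosphorylation with quantile normalisation (0.0028) and on slide 1 alone (0.044). With composition covariates, 5 genes changed sign, KIT (0.003), XBP1 (0.01), CCR7 (-0.012), HBB (0.34) and S100A8 (0.16). With the percentile over detected probes NR3C1 did (0.003), and with array weights IL5RA (0.14). Slides left out turned IL5RA (0.017, slide 1), MYB (-0.038) and TSC22D3 (-0.083, both slide 2), HBB (0.39, slide 3), and SLC18A2 (0.087), KIT (0.057) and PER1 (-0.02, all slide 4). Without the array progressive 16, TSC22D3 (-0.024) and PER1 (-0.027) changed sign. The cause was not tested for any of these. Signal over background limits the dim genes, since 26368 of 43987 probes passed the filter.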

Other observations

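The tests chosen only after the results were seen were those of 0 probes and 0 genes over other splits, of correlation between genes as the source of the list calls (the estimated correlation itself was planned), of the array progressive 16, of the glucocorticoid list without FKBP5, of the spread between mares, of sequence variants, and the choice of the genes with 2 levels and of the relations between scores. Scores of some lists, neutrophil markers among them, followed the main axes along which the arrays differed. The first axis of variation over all genes held 16.6% of the variance and the second 13.9%. On the second axis the neutrophil score had a Pearson r of -0.87 (permutation p = 1e-05, the smallest they can give, Spearman rho -0.865, permutation p = 1e-05), -0.867 without the 2 farthest mares and -0.93 to -0.742 within slides. The cell cycle score had a Pearson r of 0.754 (permutation p = 1e-05, Spearman rho 0.729, permutation p = 1e-05), 0.693 without the 2 farthest mares and 0.624 to 0.832 within slides. On the first axis the ribosomal protein score had a Pearson r of -0.764 (permutation p = 1e-05, Spearman rho -0.745, permutation p = 2e-05), -0.716 without the 2 farthest mares and -0.906 to -0.476 within slides. The 16 relations computed with the axes include these 3, each with an adjusted p of 5.33e-05. The axes were computed with the members of these lists included. A list of correlated genes can therefore follow an axis in part by construction, which these p values do not take into account. Blood cell scores were mixed. On the first axis r was -0.659 for erythroid, -0.611 for platelet, -0.386 for neutrophil, -0.372 for T cell and 0.124 for B cell scores. On the second it was 0.535 for T cell, 0.446 for B cell, -0.328 for platelet and 0.108 for erythroid scores. The ribosomal score was 1.68 on the array with the lowest 75th percentile signal and -1.31 on that with the highest. It was positive on every array with a 75th percentile of up to 484.6 and negative on every array from 496.7 upwards. Between these signals both signs occurred. The ribosomal score thus ran against the signal by which an array's values were divided. Whether the first axis itself follows signal level was not tested.

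Some list scores were related between mares. The neutrophil and cell cycle scores had a Pearson r of -0.489 (permutation p = 0.00446, Spearman rho -0.528, permutation p = 0.00227), -0.568 without the 2 farthest mares and -0.684 to -0.297 within slides. The platelet and erythroid scores had a Pearson r of 0.496 (permutation p = 0.00433, Spearman rho 0.587, permutation p = 0.00057), 0.511 without the 2 farthest mares and 0.316 to 0.92 within slides. The neutrophil and B cell scores had a Pearson r of -0.498 (permutation p = 0.00411, Spearman rho -0.466, permutation p = 0.00744), -0.435 without the 2 farthest mares and -0.709 to 0.051 within slides, so the relation did not hold within every slide. All 3 had an adjusted p of 0.00892 over the 6 relations computed. Direction within slides differed between lists, and the preset test called the interferon list lower on slides 1 and 4 and higher on slides 2 and 3, with 4 mares per group on each. Its genes had an estimated correlation of 0.501, and over all slides the list had an adjusted p = 0.948 with an estimated correlation, which was not estimated within slides.

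Of the 6 list calls with a preset correlation, chance could not be excluded as the source, since 42 of 100 splits of the arrays gave at least 6 lists, and the highest of the other splits gave 11. The smallest adjusted p with an estimated correlation was 0.663. The 6 lists had estimated correlations of 0.106 to 0.749, above the preset 0.01. In 97 of the 99 other splits the preset test called at least 1 list (median 5), against 4 of 99 with an estimated correlation. Correlation above the preset value is therefore enough to give such calls without the weaning groups. The array progressive 16 was not the source, since 5 of the 6 lists were called again in the same direction without it, all but oxidative phosphorylation. With composition covariates the cell cycle list was called (adjusted p = 0.0067) and the inflammatory and oxidative phosphorylation lists were not (0.311 and 0.85), while the neutrophil, platelet and erythroid lists make up 3 of the 4 covariates. An effect of the weaning itself stays open.

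FKBP5 ranked 7 of 9392 genes by p and was named before the data were examined. The values argue against the array progressive 16 as the whole cause, since the difference stood at 3.7 times its SE without that array. They also argue against the neutrophil, T cell, erythroid and platelet scores as the whole cause. With these scores as covariates the difference stood at 3.33 times its SE. Other cell types were not among the covariates. With slide and array row in the fit the difference stood at 3.21 times its SE, which decides nothing about position. The groups have equal numbers of arrays on every slide and in each row, so these terms leave the difference unchanged. Whether glucocorticoid signalling over the whole list rose with FKBP5 cannot be told apart from a difference in FKBP5 alone. The other 15 members differed by 0.032 (95% interval -0.18 to 0.25, permutation p = 0.856 for their score), an interval that reaches above 0. Chance stays open too, with an adjusted p of 0.996 over all genes, so a higher FKBP5 after progressive weaning is a hypothesis.

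Some genes stood at 2 separate levels across mares, with a gap of at least 1.5 on the log2 scale and at least 3 mares on each side, in 73 probes with 12 named genes, all chosen after their values were seen. EPCAM (an epithelial adhesion protein) was high in 10 mares, 6 brutal and 4 progressive, over 4 slides, with a gap of 4.83 in its probe with the widest gap. For EPCAM a sequence variant under the probe is argued against, since 100% of the high mares were also the highest in 2 probes that share no 15 bases with it, against 31.2% by chance, and its origin stays open because composition scores explained 34.5% of its variance, close to the 34.4% of the median gene. For DRB (an MHC class II chain, gap 9.86, high in 18 mares) the share was 55.6% over 9 other probes, against 56.2% by chance. For ECATH-3 (a cathelicidin, gap 4.81, high in 7 mares) it was 14.3% over 3 other probes, against 21.9% by chance. A sequence variant under the probe may set these levels. The other probes were not required to stand above background, and dim probes would also share near chance, so these shares do not decide it. No biological explanation other than blood composition was tested, and TCP11L1, the gene of the 1 probe called on slide 4 alone (3.10, adjusted p = 0.00748 in limma), also had 2 levels, with 2 brutal and 9 progressive mares high.

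Over 100 splits of the 32 arrays, the 726 probes at an unadjusted p were reached by 64, with a median of 890 and a highest count of 6723 in the others. The 726 are 2.75% of the probes, a share under the threshold of 0.05 that chance alone gives on average. The count thus showed no excess over chance. For the 0 probes and 0 genes past the threshold (limma, 726 probes and 244 genes at an unadjusted p under 0.05) the splits decide nothing, since 100 of 100 reach a count of 0, and the highest of the others gave 2366 probes and 280 genes. What the split that calls 2366 probes follows was not tested. The median log2 ratio of the variance between mares, progressive over brutal, was 0.122, as far from 0 in 50 of 100 splits (highest of the others 0.633), and 0.0593 without the array progressive 16, so the hypothesis of a wider spread after progressive weaning was not borne out.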
